A study of Bos taurus with 2 samples.

How the data were processed

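MicroRNAs (miRNAs), short RNAs that lower the output of their target mRNAs, were measured by small RNA sequencing in bovine lung. There were 2 libraries, 1 from normal lungs and 1 from collapsed lungs, and each was made from 1 pool of total RNA. Per the labels, the pools held RNA of 4 neonatal cows each, given as 500 ng per sample, from cloned or from normal animals. That the collapsed-lung pool came from the clones is read from the series text and is not stated for the sample itself. Per the labels' protocols, RNA was extracted with Trizol and libraries were made with a TruSeq small RNA kit. Pooling before sequencing left no measure of the spread between cows.

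The values came from a single table deposited by the authors, with 2271 rows used here, each with a miRNA name, a mature sequence and values for both libraries. The emptied lines of the table, 2 in number, were not analysed here. Per the submitters' processing notes, the genome build was bosTau8. The aligner, the adapter trimming and the miRNA database release are not given in the sources used here. Per the file headers, the authors gave raw read counts per row, and these counts were not all whole. In the normal-lung library 84.5% of rows held a whole number, and in the collapsed-lung library 84.3%. Names on more than 1 row with a single sequence numbered 131, and all 131 had equal values on their rows. In the normal-lung library 60 of these 131 were whole per row within 0.05 reads and 106 were whole when summed, so that reads had been divided between rows. The authors' normalized reads, a signal scaled per library per the file headers, equalled the raw reads divided by 1.21 in the normal-lung library and by 0.823 in the collapsed-lung library. How these factors were chosen is not given in the sources used here. In 27 rows the normalized values were not the row's own reads over the factor within 2%, and the sequence of each of these rows also stood under another name. Per the file headers the authors also deposited a fold change (the ratio of collapsed to normal normalized reads), its log2 value, and p-values from a chi-square test and a Fisher's exact test on the reads of the 2 libraries. These p-values compare 2 libraries and not the conditions, and they are not used as evidence here.

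Rows were scaled to reads per 1000000 of the library's reads in the table (RPM). For each row the ratio of the collapsed-lung to the normal-lung library was taken with an exact conditional binomial 95% interval, for which reads were rounded to whole numbers. The interval and every floor cover counting error only, since reads amplified by PCR without molecular identifiers are not independent molecules. A row was measured when its mean over the 2 libraries was at least 10 RPM. It was called higher or lower in the collapsed-lung library when the ratio was at least 2 or at most 0.5 and the interval left out 1. Where a library had no reads for a row, 0.5 read was added to both. No count model and no test between the conditions was used, because 1 library per group leaves no residual degrees of freedom. Reads were kept as deposited, and rows named for cattle (bta), for other species or as predicted miRNAs (PC) all entered the calls. The plan worded this in 2 ways, once with cattle rows and rows without a species prefix only and once with rows of other species counted too, and the wider reading was taken after the data were seen. The narrower one gives 11 higher and 9 lower calls in place of 17 and 14. Names in the text leave out the bta prefix and the suffix for end or base differences. An ending p3 or p5 in the deposited names is read here as the 3p or 5p arm of a precursor.

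There were 16 lists of miRNAs, fixed before the data were examined, as were the choices above apart from the rows of other species. The let-7, miR-17-92, miR-200, miR-34 and miR-449 and miR-26/29/30 families stood for developmental and epithelial miRNAs. The DLK1-DIO3 cluster and other imprinted loci were listed because the pools differ in cloning, and pluripotency miRNAs because clones come from reprogrammed nuclei. Mesenchyme, endothelium, striated muscle, erythroid blood, leukocytes, neural and neuroendocrine cells, liver, and hypoxia and stress made up the others. For each of the 15 lists with at least 3 measured rows, the median log2 ratio was given with its percentile among 10000 random lists of the same size, matched on mean expression in 10 bins. The percentile describes these 2 libraries and is no test. A name repeated in the table, or a sequence held under different names, counted as separate rows of a list. Such rows are not independent, and neither are the arms of a precursor or the members of a gene cluster. The random lists drew single rows, so a percentile can overstate how unusual a list is. The named miRNAs were the 12 rows called higher and the 12 called lower that ranked first by the interval bound nearest to 1, the 10 most abundant names of each library, and up to 4 members of each list, called members first and then the most abundant. A miRNA named outside this rule is said to have been chosen after its values were seen. Both arms of a precursor were set beside each other where both were measured under bovine names, against 1000 draws of random pairs matched on abundance, and again under names of all species, with arms that share no 8 bases in a row. Seed sites in the surfactant protein C and TTF-1 mRNAs were planned and were not analysed here, as they need 3' UTR sequences.

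The calls were tested on simulated data for the collapsed against normal comparison, with Poisson counts drawn for the 2271 rows at the real depths and 50 rows changed per fold and direction. All of the rows raised 4-fold and 3-fold were called (100%), and 90% of the rows lowered 3-fold and 90% of those lowered 4-fold. None of the 289 measured rows left unchanged was called. The intervals held the true ratio in 95.2% of rows. The simulation held counting error alone and used the true scaling. It therefore does not bear on differences between pools, divided reads or a wrong scaling. Alternatives covered median-of-ratios factors, a trimmed mean of log ratios, totals without the most abundant miRNA, the authors' normalized values, other minimum levels, fold thresholds and pseudocounts, summed rows of 1 mature name, and cattle rows alone. Neighbouring miRNA genes were taken from a RefSeq gene table of assembly ARS-UCD2.0, which is not the submitters' build, so no coordinates are given. Computations used Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9.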

Results

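Small RNA libraries of normal and collapsed lungs of neonatal cows were compared to find miRNAs whose levels differ in a cloned bovine model of neonatal respiratory distress. The study's stated interest is in miRNAs that target surfactant protein C (SFTPC), a protein of alveolar type II cells, and TTF-1, a transcription factor of lung epithelium. The normal-lung library held 4550911 reads in the table and the collapsed-lung library 2822876. Rows with reads numbered 1944 and 1750, respectively. A row with 3 reads stood at 0.659 reads per 1000000 (RPM) in the normal-lung library and at 1.06 RPM in the collapsed-lung library, and rows without reads allow levels up to these values. With 1 pool per group, no difference below has a replicate check.

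A small number of miRNAs made up most of both libraries, and largely the same ones. miR-143, a smooth muscle and fibroblast miRNA, took 14.6% of reads in the normal-lung library (exact binomial 95% interval 14.61 to 14.68%) and 13.5% in the collapsed-lung library (13.46 to 13.54%). miR-26a, summed over its 2 rows, took 11.2% and 10.7%, and let-7a-5p, summed over 3 rows, took 4.15% and 4.36%. The endothelial miR-126-3p took 4.04% and 4.06%. miR-30a-5p took 4.25% in the normal-lung library and 3.24% in the collapsed-lung library. The remaining names among the most abundant in both libraries were miR-99a-5p (3.63% and 3.36%), miR-27b (3.52% and 3.66%), let-7f (2.75% and 2.80%) and miR-199a-5p (2.31% and 2.77%). let-7b, at 1.99% in the normal-lung library, was among its 10 most abundant names, and in the collapsed-lung library its place was taken by miR-21-5p, at 3.72%. The 10 most abundant names of each library shared 9 names and held 52.5% and 52.2% of reads. Rows with bovine names held 97.8% and 97.7% of reads.

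Across the table, miR-34b and miR-34c were about 3-fold lower in the collapsed-lung library, miR-146a and miR-92b were about 2-fold lower, and a set of scarce miRNAs was higher. Of 487 measured rows, 17 were called higher and 14 lower in the collapsed-lung library. The levels of most miRNAs differed little, with 79.7% of measured rows within 1.5-fold and a median log2 ratio of 0.09 (quartiles -0.18 and 0.34). The counting interval left out 1 in 297 of the 487 rows, so depth alone resolves differences much smaller than 2-fold. The balance of calls depended on the scaling of the libraries, which moved log2 ratios by -0.16 with median-of-ratios factors, -0.12 with a trimmed mean and -0.13 with the authors' normalized values, in which 27 rows of the table carry another name's values and moved otherwise. The calls were then 12 higher and 21 lower, 14 higher and 20 lower, and 15 higher and 21 lower, in that order.

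**Figure D1:**
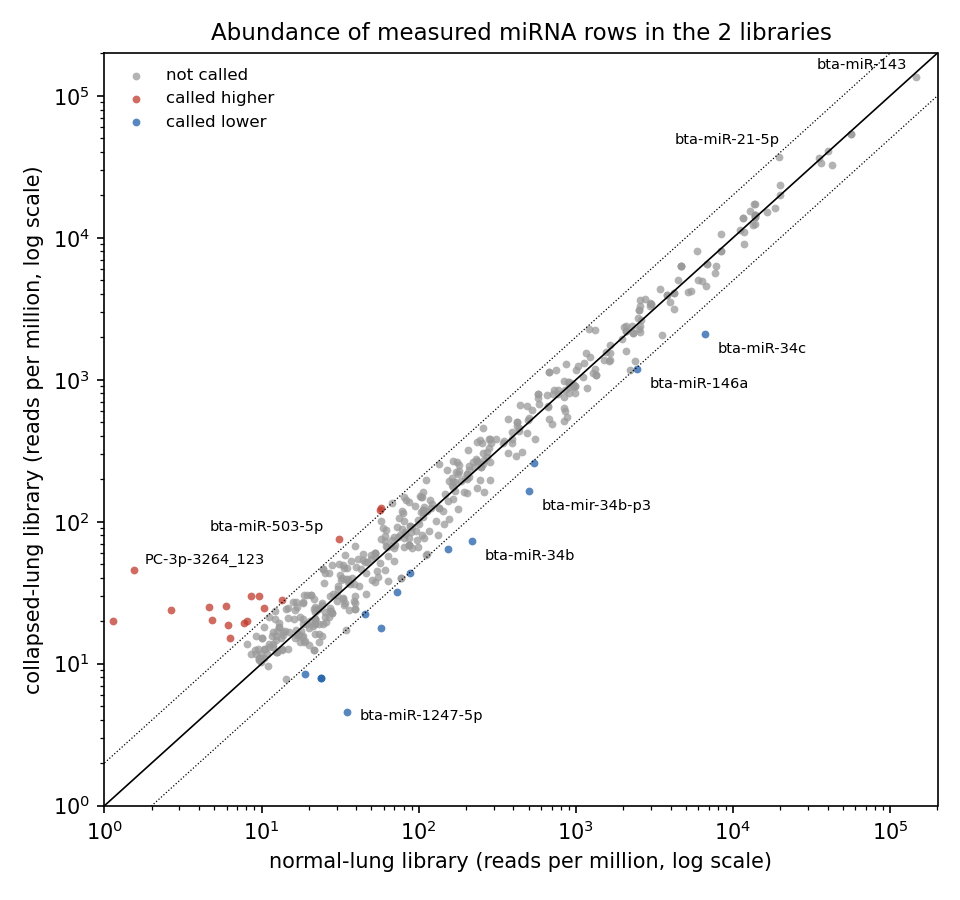
Each point is a measured row, with its level in RPM in the normal-lung library on the horizontal axis and in the collapsed-lung library on the vertical axis, both on log scales; the solid line marks equal levels and the dotted lines a 2-fold difference. Most rows follow the line of equal levels, miR-34c lies below it at 6596 against 2105 RPM, and the rows called higher reach at most 126 RPM in the collapsed-lung library.

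The rows called lower included abundant miRNAs. miR-34c stood at 6596 RPM in the normal-lung library and at 2105 in the collapsed-lung library, 3.13-fold lower (95% interval 3.05 to 3.22). miR-34b was 2.98-fold lower (2.57 to 3.48), its 3p arm 3.05-fold lower (2.76 to 3.38), and the row named for the human 3p arm of miR-34c 2.30-fold lower (1.81 to 2.93). Rows of miR-34b or miR-34c under any species name made up 6 of the 14 lower calls, in 5 distinct sequences, since the opossum name mdo-miR-34b-5p, at 2.99-fold, stood on 2 rows with equal values. miR-146a, which dampens inflammatory signalling, was 2.06-fold lower (1.98 to 2.14), from 2456 to 1192 RPM. miR-92b was 2.08-fold lower (1.92 to 2.26), miR-504 2.39-fold (2.03 to 2.83) and miR-490 3.23-fold (2.38 to 4.46). The fold was widest for miR-1247-5p, at 7.63-fold lower (4.34 to 14.7), on 160 reads against 13. hsa-miR-224-3p, at 2.03-fold (1.66 to 2.51), and miR-2284ab, at 2.05-fold (1.54 to 2.76), lay close to the threshold, and both calls were lost with a pseudocount of 5 reads, at log2 ratios of -0.98 and -0.96.

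The rows called higher were scarce, and 13 of the 17 had fewer than 100 reads in both libraries. The predicted miRNA PC-3p-3264_123, with the sequence GAAATCCGAACGAACTTTTTGGA, had 7 reads in the normal-lung and 129 in the collapsed-lung library, 29.7-fold higher (14 to 75.4). The same sequence without its last base, GAAATCCGAACGAACTTTTTGG, stood under bta-mir-2284z-6-p3, 17.8-fold higher (7.43 to 58.8), and under bta-mir-2284aa-3-p3, 4.28-fold higher (2.73 to 6.96). These 3 rows carry names of the large bovine miR-2284 family of closely related miRNAs or share its sequence, so their separate values are uncertain. With the authors' normalized values bta-mir-2284z-6-p3 was at a log2 ratio of 1.97 in place of 4.15, since the table gives it the normalized values of the other name. With median-of-ratios factors or a trimmed mean it fell under the minimum, at 9.57 and 9.82 RPM, and was not called. hsa-miR-4443 was 9.0-fold higher (4.83 to 18.3), ggo-mir-421-p5 5.45-fold (3.31 to 9.34), miR-6522 4.18-fold (2.51 to 7.18), miR-383 3.47-fold (2.35 to 5.22), miR-2440 3.11-fold (2.14 to 4.59) and cgr-miR-1260 3.02-fold (1.86 to 4.92). The sequences of hsa-miR-4443, miR-2440 and cgr-miR-1260 are 16 nt long, shorter than most mature miRNAs. Of 9 measured rows of at most 17 nt, 4 were called higher and 0 lower, with a median log2 ratio of 0.77, against 13 higher and 14 lower of 478 longer rows, with a median of 0.08. All rows of at most 17 nt took 0.032% of reads in the normal-lung and 0.051% in the collapsed-lung library. Better covered were miR-503-5p, 2.41-fold higher (1.94 to 3.0) on 142 against 212 reads, mmu-miR-551b-3p, 2.19-fold (1.86 to 2.58), and miR-21-3p, 2.12-fold (1.8 to 2.5). The calls of the last 2 depended on scaling, since the median-of-ratios factors gave log2 ratios of 0.98 for mmu-miR-551b-3p and 0.93 for miR-21-3p. Rows under bovine names made up 10 of the higher and 9 of the lower calls.

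**Figure D2:**
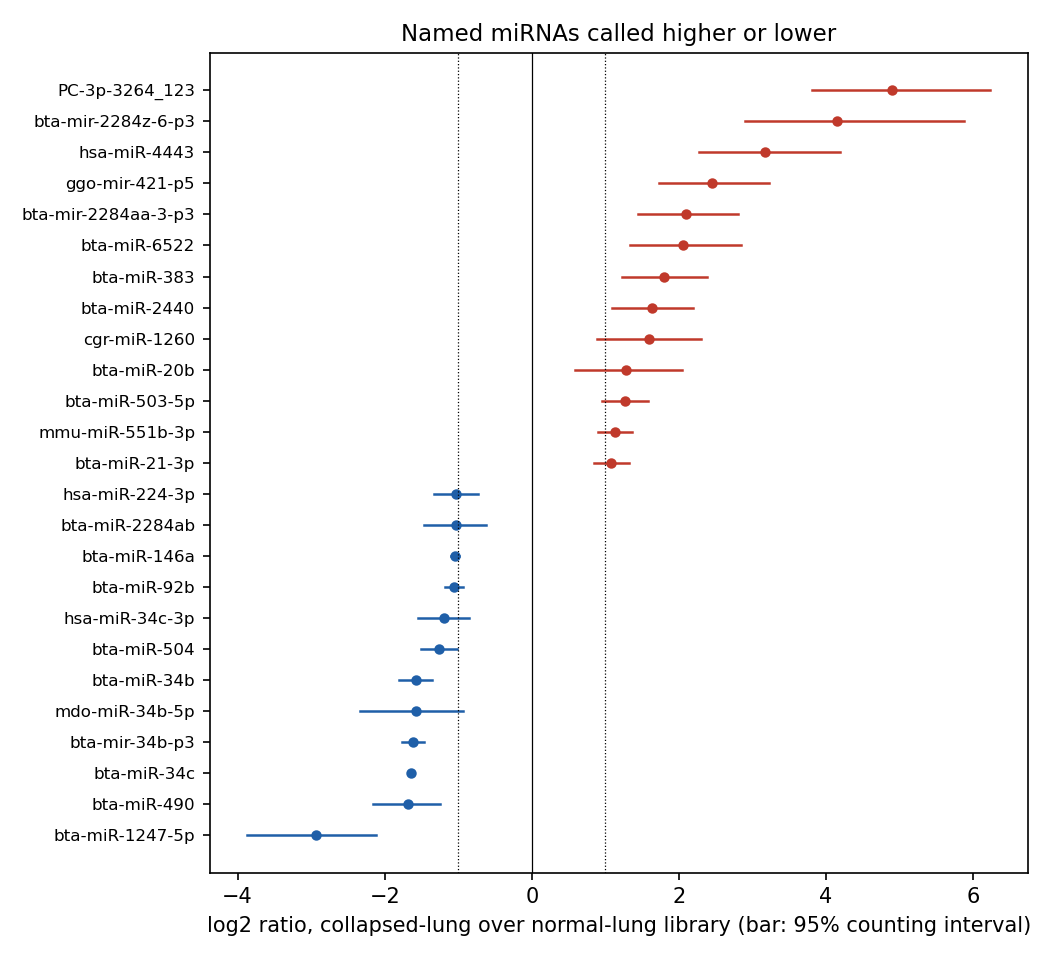
Points show the log2 ratio of the collapsed-lung over the normal-lung library for the named rows called higher or lower, and bars the 95% counting interval; dotted lines mark a 2-fold difference. The intervals of miR-34c and miR-146a are narrow, whereas PC-3p-3264_123, on 7 against 129 reads, spans 14-fold to 75.4-fold.

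Among the fixed lists, the miR-34 and miR-449 family and the miR-26/29/30 families had the lowest median log2 ratios. Members of the former other than miR-34a mark multiciliated airway epithelium, and the latter are abundant in maturing lung. Each of the 4 other scalings moved ratios down, so no list median below 0 could rise above 0 with them. The miR-200, DLK1-DIO3, striated muscle and erythroid blood medians stayed below 0 in the same way. In the miR-34 and miR-449 family 3 of 7 measured rows were called lower and 4 were not called, and the median log2 ratio of -0.55 lay at percentile 0.14 of 10000 random matched lists. Apart from miR-34a its rows belong to gene clusters, miR-34b with miR-34c and the miR-449 members together, so this percentile can overstate how unusual it is. miR-449a was at -0.55, miR-449c at -0.49 and miR-449b at -0.39, all 3 chosen after their values were seen, and miR-34a was at 0.22. The miR-26/29/30 list had 15 measured rows of 12 names, all with log2 ratios below 0 and none called when scaled to totals. Its median of -0.37 was below that of each of 10000 random lists (percentile 0). Within it the miR-29 family, which targets collagen and other matrix mRNAs, stood lowest. miR-29a was 1.88-fold lower (1.8 to 1.95), from 2211 to 1178 RPM, miR-29b 1.92-fold (1.55 to 2.39) and miR-29c 1.91-fold (1.60 to 2.29), all short of the 2-fold threshold and chosen after their values were seen. Under 3 of the 4 other scalings these 3 were called lower, at log2 ratios from -1.10 to -1.02. miR-30a-5p was 1.31-fold lower (1.30 to 1.32), and miR-26a, miR-26b and miR-30e-5p were at log2 ratios of -0.06, -0.12 and -0.14.

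The medians of the miR-17-92, mesenchyme, hypoxia and stress, and other imprinted lists were above 0 under all 5 scalings. So were those of the endothelium list and of the neural and neuroendocrine list, given below. The shift of -0.16 by median-of-ratios factors takes away most of these 2 medians, of 0.20 and 0.18. The neural median was also less than its rows' median counting half-width of 0.29, so its sign lies within counting error. The miR-17-92 and paralog clusters, linked to proliferation and early lung development, had a median log2 ratio of 0.32 over 15 rows of 13 names (percentile 99.3). As these are gene clusters, this percentile too can overstate how unusual the list is. In this list 1 row was called higher, miR-20b at 2.42-fold (1.5 to 4.14) and a mean of 10.7 RPM, and 14 were not called, among them miR-25 at 0.42, miR-92a at 0.18 and miR-20a at 0.27. With median-of-ratios factors miR-20b was at 9.94 RPM, under the minimum, and the list had no call. The mesenchyme list had a median of 0.33 over 11 rows of 8 names (percentile 99.8) with no row called, and both arms of miR-199a were repeated in it. In it miR-199b (0.33), miR-10a (0.34) and miR-199a-5p (0.26) went one way, and miR-143 (-0.12) and the smooth muscle miRNA miR-145 (-0.58, chosen after its value was seen) the other. In the hypoxia and stress list 1 of 7 rows was called, miR-21-3p, and the median was 0.27 (percentile 88.5). With median-of-ratios factors this median was 0.12, less than the rows' median counting half-width of 0.24, and miR-21-3p was not called. Its partner arm miR-21-5p, a miRNA induced in injured and fibrotic tissue, stood at 19674 RPM in the normal-lung and 37206 in the collapsed-lung library, 1.89-fold higher (1.87 to 1.91) and not called. miR-22-3p was at 0.50, and miR-210, a marker of hypoxia, was at 0.15 with an interval of 0.986 to 1.24-fold that includes 1. The other imprinted loci had a median of 0.51 over 3 rows (percentile 96.4), none called, with miR-483, from the IGF2 gene, at 1.85-fold (1.60 to 2.13), miR-296-3p at 0.51 and miR-335 at -0.14.

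**Figure D3:**
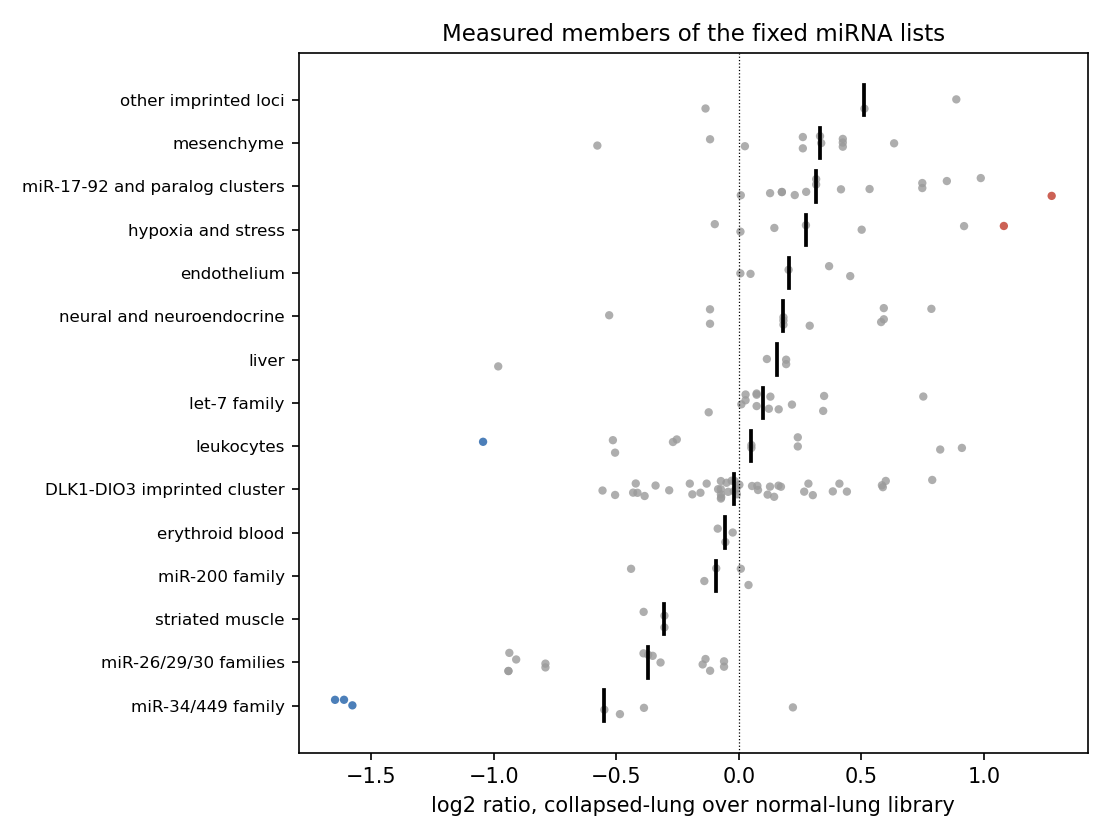
Each point is a measured row of a fixed list at its log2 ratio of the collapsed-lung over the normal-lung library, red where called higher and blue where called lower, and each bar is the median of the list. The miR-34 and miR-449 family has the lowest median, -0.55, and the 3 other imprinted loci the highest, 0.51.

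The DLK1-DIO3 cluster, a maternally expressed imprinted locus, had 44 measured rows of 42 names and none was called. Its median log2 ratio was -0.02 (percentile 6.60), with miR-127 at 0.27, miR-411a at -0.02, miR-380-3p at -0.19 and miR-379 at -0.08. The let-7 family, which is known to increase as tissues differentiate, had none of 14 rows called and a median of 0.10 (percentile 89.3), with let-7b at 0.01, let-7f at 0.03, let-7a-5p at 0.07 and let-7g at -0.12. The miR-200 family of epithelial cells had none of 5 rows called and a median of -0.09 (percentile 20), with miR-200b at 0.01, miR-200a at -0.09, miR-200c at -0.14 and miR-141 at -0.44. The medians of the let-7, leukocyte and liver lists were smaller than the shift of -0.16 that median-of-ratios factors gave all rows. They turned negative by that shift alone, at -0.06, -0.10 and -0.0013, so their sign depends on the scaling chosen. None of the pluripotency miRNAs was measured, and the single row present had 1 read in the normal-lung and 0 in the collapsed-lung library.

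The endothelium list had none of 5 rows called and a median of 0.20 (percentile 75.1), with miR-126-3p at 0.01, miR-126-5p at 0.45, miR-221 at 0.37 and miR-222 at 0.05. The red blood cell miRNAs miR-451, miR-486 and miR-144 were at -0.09, -0.02 and -0.05, none called, with a median of -0.05 (percentile 39.8). The leukocyte list had 1 of 11 rows called, miR-146a lower, and a median of 0.05 (percentile 36.8) that became -0.25 when repeated rows of a name were summed. Its members went both ways, with miR-142-5p at -0.25, the lymphocyte miRNA miR-150 at -0.50 and miR-181a at 0.05. Striated muscle had none of 3 rows called (median -0.30, percentile 11.2), with miR-499 at -0.39 and miR-133a at -0.30. The neural and neuroendocrine list had none of 11 rows called and a median of 0.18 (percentile 74.7), with miR-375, of neuroendocrine cells, at -0.53, miR-128 at -0.12, miR-7 at 0.18 and miR-182 at 0.58. The liver list had none of 4 rows called and a median of 0.15 (percentile 64.2), with miR-192 at 0.11 and miR-194 at 0.19. Its member miR-122 was 1.97-fold lower (1.42 to 2.78) on 156 against 49 reads, and it was called lower under each of the 4 other scalings, at log2 ratios from -1.14 to -1.0.

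Both arms of a precursor come from a single transcript, and most of their ratios lay close together here. Over 30 precursors with both arms measured under bovine names, the median absolute difference of the arms' log2 ratios was 0.24, against 0.40 for random pairs matched on abundance (95% of 1000 draws between 0.25 and 0.60). The arms lay within 0.5 of each other in 26 of 30 precursors and on the same side of 0 in 22. With names of all species, a wider set chosen after the result was seen, the median difference over 100 precursors was 0.23 (random pairs between 0.33 and 0.53), and 85 were within 0.5. The largest gap, 2.45, lay between ggo-mir-421-p5, called higher, and miR-421, at a ratio of 0.999 (0.844 to 1.18).

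The authors' deposited table set apart 78 rows as different, 35 up and 43 down in collapsed lungs, all with an authors' p of at most 0.05 in at least 1 of 2 tests and at least a 2-fold difference. Of these 78 rows, 29 were called here, 42 were under the minimum of 10 RPM, and 7 were measured and not called. All of the 7 were down in the authors' deposited table, among them miR-29a, miR-29b and miR-29c, at log2 values of -1.04, -1.07 and -1.06 in the authors' deposited table. The ratio of the authors' factors was 1.48, against 1.61 for the totals, which lowers log2 ratios by 0.13 relative to the totals, apart from the 27 rows with another name's values, and takes these 7 rows past the 2-fold threshold. Outside the authors' section 2 rows were called here, both higher, miR-21-3p and hsa-miR-130b-5p, the last of which was chosen after its value was seen.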

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

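Leaving out rows named for other species was added as an alternative after seeing the data, although 1 of 2 wordings of the plan had it as the first choice, and the other alternatives here were planned. No paired analysis was possible because there is 1 library per group. Of the 17 higher and 14 lower calls, other scalings kept 12 to 17 of the higher and all 14 of the lower, with 12 to 17 higher and 15 to 21 lower in all. Each of these scalings moved ratios down, so that the lower calls were kept is no support for them. A pseudocount of 5 reads gave 17 and 11, and summing rows of a mature name 18 and 14. Filters and thresholds moved both counts by construction, since each admits more or fewer rows. With no minimum there were 49 higher and 31 lower, with a minimum of 100 RPM 0 and 6, with cattle rows only 10 and 9, and without other-species rows 11 and 9. A ratio of at least 1.5 gave 62 and 35, and a ratio of at least 4 gave 6 and 1. Of the 25 named miRNAs that were called, 0 changed sign where measured. A call needed a 2-fold difference and the largest shift of a scaling was -0.16, so this could hardly have come out otherwise. Another scaling or pseudocount ended 6 calls, those of mmu-miR-551b-3p, miR-21-3p, hsa-miR-224-3p and miR-2284ab by their ratios and those of bta-mir-2284z-6-p3 and miR-20b because 2 scalings and 1 scaling, respectively, put them under 10 RPM. The 100 RPM minimum ended 19 of the 25, and miR-122 gained a call. List medians moved beyond their counting error, after the shift of the scaling was taken off, in these cases. With a minimum of 100 RPM the let-7 median was 0.073, the miR-34 and miR-449 median -1.58, as only abundant members stayed, the miR-26/29/30 median -0.23 and the neural median -0.12. With no minimum the miR-26/29/30 median was -0.43 and the leukocyte median -0.25. With rows summed the let-7 median was 0.14, the mesenchyme median 0.30 and the leukocyte median -0.25. The leukocyte and neural medians changed sign because the rows in these lists changed. The leukocyte median of 0.05 was the value of miR-181a, a repeated name, and -0.25 was that of miR-142-5p. At 100 RPM the neural list kept only miR-375, at -0.53, and miR-128, at -0.12. The seed-site alternatives were not run.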

Other observations

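The tests of scaling and of reads moved between similar rows for the miR-34 and miR-29 patterns, the test on ciliated cells, the read balance of the third pattern and the values by gene neighbourhood were chosen after the result was seen. The members of several miRNA gene clusters lay on the same side of 0, though not always at like ratios. The cluster of miR-424, miR-503, miR-542 and miR-450b, of which miR-424 and miR-503 are known to restrain the cell cycle, had log2 ratios from 0.40 to 1.27 in its 4 names, with miR-503 called higher. Only names with a single gene entered the clusters. The related miR-450a, not among these names and chosen after its value was seen, was at 0.30. The neighbours miR-363 and miR-20b were at 0.99 and 1.28, and miR-182, miR-183 and miR-96, miRNAs of sensory epithelia, were at 0.58, 0.79 and 0.29. Both arms of miR-130b, chosen after their values were seen, were called higher. The ratio was 2.38-fold (1.64 to 3.55) for miR-130b and 2.09-fold (1.48 to 2.97) for hsa-miR-130b-5p, which 3 of the 4 other scalings did not call. The cluster of miR-224, miR-452 and miR-3431 was on the lower side, from -0.81 to -0.68. Of 274 bovine names measured, 265 matched a gene of the RefSeq table by name and 235 had a single gene. Over 45 pairs of neighbours within 10 kb, without the largest cluster of 30 names, the median absolute difference in log2 ratio was 0.20, against 0.40 for random pairs matched on abundance (95% of 1000 draws between 0.27 and 0.57). Over all 74 pairs it was 0.22.

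In the leukocyte list, miR-155 and miR-146b were higher in the collapsed-lung library at log2 ratios of 0.91 and 0.82, whereas miR-146a, miR-223 and miR-150 were lower at -1.04, -0.51 and -0.50. Of these 5 only miR-146a was called, and miR-155, miR-146b and miR-223 were chosen after their values were seen. miR-146a and miR-146b differ little in sequence and come from different genes, and both are induced by inflammatory signalling. The bovine miR-2284 and miR-2285 rows, 147 in number, had 8204 reads in the normal-lung and 3811 in the collapsed-lung library, pooled 1.34-fold lower (1.28 to 1.39).

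The first pattern is the lower level of miR-34b and miR-34c, whose rows pooled were 3.11-fold lower (3.03 to 3.19). A wrong scaling would move all rows alike. Less the median of all measured rows, the highest upper bound of the log2 ratios of miR-34b and miR-34c was -0.95, so a uniform shift does not set them apart. This was largely fixed in advance, because the rows were picked for low ratios. A linear trend on GC content and length was weak across measured rows, with an r squared of 0.024. After its removal the highest log2 ratio was -1.28, which so weak a trend could hardly change. Other effects of sequence were not tested. Both 3p arms, which differ in sequence from the 5p rows, were lower too, with a highest upper bound of the ratio of 0.552. Both rows were among the lower calls that make up the pattern, and such a call needs a bound below 1. This outcome was thus fixed in advance and leaves reads moved between similar rows undecided. A smaller share of ciliated cells may contribute, but the pooled ratio of miR-449a, miR-449b and miR-449c was 0.690 with a lower bound of 0.640, above the upper bound of 0.330 for miR-34b and miR-34c, which argues against it as the whole cause if these cells make both sets in a fixed proportion. Lower transcription of the miR-34b and miR-34c gene in collapsed lungs stays open as a hypothesis, as do cloning and differences between single cows.

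The second pattern is the joint lower level of the miR-29 family. Less the median of all measured rows, the highest upper bound of its log2 ratios was -0.31, and the median after removal of the trend on GC content and length was -1.01. Both results were largely fixed in advance, since the family was picked for its low ratios and the trend was weak. The 5p rows of all species names, which differ in sequence from the 3p rows, were also lower when pooled. Their ratio was 0.555, with an upper bound of 0.715. Most of the pooled reads belonged to miR-29d-5p, a member of the family picked for its low ratios. The other 5p rows were lower too, but on few reads. This outcome was thus largely fixed in advance and leaves reads moved between similar rows undecided. By its nature a uniform scaling cannot set the family apart from other rows, but it decides whether miR-29a, miR-29b and miR-29c pass the 2-fold threshold. So weak a linear trend could hardly change their ratios. Technical explanations beyond these and moved reads were not tested. A lower output of the miR-29 genes in collapsed lungs is a hypothesis that these 2 libraries may fit but cannot set apart from the makeup of each pool.

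The third pattern is the sequence GAAATCCGAACGAACTTTTTGG, alone or with an added A, whose 3 rows had 39.3 reads in the normal-lung and 258 in the collapsed-lung library. The single other row within 2 edits rose as well, from 2 reads in the normal-lung to 14 in the collapsed-lung library. It held reads for a loss of at most 4.48 (upper bound) at the depth of the collapsed-lung library, against 233 reads gained. So scarce a row could not have been the source, and this comparison could not have come out otherwise. Reads moved from more distant rows stay open, untested, as the other bovine miR-2284 and miR-2285 rows together were 1.38-fold lower (1.32 to 1.43). A sequence variant that differs between the cows could give such a gap, and rows whose name marks a base difference were called in 4 of 49 cases, 2 of them rows of this sequence, against 26 of 396 for the others (one-sided Fisher's exact test across rows, p = 0.426, odds ratio 1.26), and the upper bound of 3.93 for the odds ratio leaves open whether variants differ between the pools in general. Transcription in the tissue stays open as well, untested, since each pool is a single library.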
